A study of Mus musculus with 5 samples.

How the data were processed

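Total RNA from the liver of 5 male mice was measured on Affymetrix whole-transcript arrays, 1 array per mouse. Per the labels, streptozotocin had been injected at 65 mg/kg on 5 days in a row at an age of 10 to 16 weeks, and bezafibrate was given in the food for 8 weeks, beginning 2 weeks after the injections. The protocol names 0.25% and 0.5% bezafibrate by weight and does not say which of these a mouse received, so the amount was not used. RNA was extracted with a column kit that included a DNase step and labelled with biotin, per the labels' protocols. The titles number the mice 1 to 5, and these numbers serve as names only.

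The values are on the log2 scale and were deposited by the authors as 1 number per probe set and array. Per the submitters' processing notes, the tools were RMA and Affymetrix Expression Console 1.2, with no order or setting given. RMA corrects the background, makes the distributions of the arrays alike and summarises the probes of a probe set, so a difference of 1 is a 2-fold difference in signal, and differences near the background are compressed. The quantiles of the 5 arrays were close but not exactly equal, so whether other arrays entered the same normalization is not given in the sources used here. Scanner images and probe-level signals were not analysed here.

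The table held 35556 probe sets. The platform annotation gave exactly 1 gene symbol to 21789 of them, several to 1621 and none to 12146. Of the probe sets with 1 symbol, 21698 were matched by gene ID to the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names and for which genes lie on the Y chromosome. Genes were named from probe sets with 1 symbol only, which left 19938 genes, 999 of them with more than 1 probe set. For these, the probe set with the highest mean stands for the gene.

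A brightness floor was taken on each array as the 95th percentile of 1212 probe sets of olfactory and vomeronasal receptor genes, which liver is not known to express. It lay between 5.58 and 6.07 on the log2 scale. The levels of different probe sets depend on their probes and were not compared with each other. Arrays carry no count of molecules, so the number of arrays limits the precision.

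With 1 group there is no contrast between treatments, and the tests concern the spread between mice. For single genes, an intercept-only model was fitted with limma 3.58.1 (lmFit) in R 4.3.3, and the variance between the 5 arrays, on 4 residual degrees of freedom, was compared by an upper-tail F test with the variance expected at the same mean level. The expected variance came from the robust fit of limma (fitFDistRobustly, with statmod 1.5.0) with the mean log2 value as covariate. Its prior degrees of freedom were 6.21. Tested were 14589 probe sets of 13339 genes whose mean lay above the floor of the means, 5.76, with Benjamini-Hochberg adjustment at 0.05. No technical replicates were measured, so the spread between mice includes the technical spread. The p-values describe these 5 livers.

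For gene lists, each gene was centred on its mean over the 5 mice, and the centred values were averaged over the list, which gives 1 deviation per mouse. The SD of the 5 deviations was set against that of 10000 random lists of the same size, drawn from the tested genes in 20 bins of mean level. The share of random lists at or above it is called the permutation p here (upper tail). It was adjusted by Benjamini-Hochberg over the 37 lists with at least 5 tested members. Genes were drawn at random and mice were not permuted, so it compares a list with other genes of these 5 livers. Where 0 of the 10000 random lists reached the list, the share was 9.999e-05, which gave the smallest adjusted p, 0.000411. Lists that passed 0.05 are said to have varied together. Of 39 lists of 794 distinct genes, covering metabolic pathways, stress and immune responses, sex bias, clock phase, liver zones and cell types, 702 genes had a probe set with 1 symbol and 626 were tested. Genes can belong to more than 1 list, and genes are not independent of each other. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.

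The lists, the tests, 25 alternative settings and the rule for named genes were fixed before the data were examined. The rule named 24 metabolic and liver genes in all cases, of which 20 are reported here. It also named the 15 genes with the largest ratio of variance to expected variance among those that passed the test, leaving out predicted genes, small RNAs, ribosomal protein genes, immunoglobulin and receptor genes, which were only counted. It further named the 4 members with the largest SD of each list that varied together, up to 2 from each other list, and each member of a list that varied together whose own variance passed the test. Alternatives were another normalization (quantile, or each array centred on its median), other filters on dim probe sets, other variance fits, other ways to summarise a list and to draw random lists, the mean over all probe sets of a gene, and leaving out each mouse in turn. A further pair of alternatives was added after the data had been seen.

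Both tests were tested on simulated data. With variances drawn from the fitted distribution, the F test called 41 of 100 probe sets whose SD had been multiplied by 5, 81 of 100 multiplied by 10, and 5 of the 14389 others. With no probe set changed, it called 0 of 14589. These probe sets were drawn independently of each other from the model that the F test assumes. The counts thus do not show how it behaves on correlated genes. The list test called 20 of 20 lists of 20 genes given a shared deviation with an SD of 0.15. It called 0 of 380 lists without one, of which 3.42% had an unadjusted p under 0.05. Several lists that passed had a smaller SD, down to 0.0554, and smaller shared deviations were not simulated. The lists without a shared deviation do not show how the list test behaves on correlated genes.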

Results

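Gene expression was measured in the liver of 5 male C57BL/6N mice aged 5 to 6 months. All 5 had been given streptozotocin, a compound toxic to the insulin-producing beta cells of the pancreas that is used to induce diabetes, and then bezafibrate, a lipid-lowering fibrate that activates peroxisome proliferator-activated receptors (PPARs). The series concerns how bezafibrate affects metabolism in diabetic mice. Livers of other treatments were not analysed here. The measurements thus give the level of each gene in doubly treated livers and how far mice given both compounds differed, and no effect of either compound. Neither the amount of bezafibrate (0.25% or 0.5%) nor the exact age at injection (10 to 16 weeks) is given per mouse. Differences in these cannot be told apart from other differences between the mice. Array medians lay between 6.22 and 6.31 on the log2 scale of the deposited values. Pearson's r of array pairs across probe sets lay between 0.971 (mice 1 and 4) and 0.993 (mice 1 and 2), where probe sets are not independent replicates. No pair of arrays had more than 0.537% identical values.

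Transcripts of the Y chromosome matched the male label of the mice. Kdm5d had a mean of 7.31 ± 0.21 (SD, n = 5), Eif2s3y of 8.88 ± 0.22 and Uty of 7.90 ± 0.20, all 3 above the brightness floor on all arrays, while Xist, which is transcribed from an inactive X chromosome, had a mean of 4.25 ± 0.07. Uty and Xist were picked for printing after their values were seen. The list of Y-linked genes and Xist had 3 tested members, too few for the list test. Over all lists, 597 of 702 genes exceeded the floor in all 5 livers, against 11962 of all 19938 genes.

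The genes that differed most between the livers for their level included Sprr1a, Lcn2, Saa2, Orm2, Pdk4 and Srsy. Sprr1a, which encodes a small proline-rich protein of cornified epithelia, spanned 17.5-fold, with a mean of 9.66 ± 1.52 (SD, n = 5) and values of 7.78 in mouse 3 and 11.90 in mouse 5. Among genes of secreted acute-phase proteins, Lcn2 (lipocalin 2) spanned 7.04-fold with an SD of 1.27, Saa2 (serum amyloid A2) 9.96-fold with an SD of 1.35, and Orm2 (orosomucoid 2) 5.77-fold with an SD of 0.99. Pdk4, which encodes a kinase that inhibits pyruvate dehydrogenase, had a mean of 10.99 ± 0.86 (n = 5) and spanned 4.61-fold. Srsy, a multicopy gene of the Y chromosome, had a value of 9.63 in mouse 4 and values of 5.41 to 7.41 in the other mice, and stayed below the floor in at least 1 of them. Of 67 probe sets assigned to several genes that lie mainly on the Y chromosome, 98.5% were also brightest in mouse 4, as were 76.0% of the 1212 receptor probe sets.

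In all, 52 probe sets of 38 genes, out of 14589 probe sets of 13339 genes, had a variance above that expected at their level (F test with limma's robust variance fit, Benjamini-Hochberg 0.05), and 925 probe sets (6.34%) had an unadjusted p under 0.05. All 15 tested Srsy probe sets, of 19, were among the 52, and 5 of the 38 genes are of kinds that were only counted. The filter on the mean over mice favours probe sets that 1 mouse raises, as mouse 4 did here, so this share is no separate result. Some Srsy probe sets had the same mean and SD as another (6.19 and 1.82, for example) and are not independent calls. The count was 142 with each array centred on its median, 18 with the stricter filter on dim probe sets or without the robust step, 24 without the trend on level, and 0 (1385 at an unadjusted p under 0.05) when limma tested all probe sets with or without 1 symbol. It also changed when 1 array was left out. Without mouse 4, limma called 0 probe sets (864 at an unadjusted p under 0.05) and the adjusted p of the 25 named genes that had passed lay between 0.0883 and 0.228. The SDs of 21 of these 25 genes were larger without mouse 4, and those of Cyp2b13 (0.76 instead of 0.86), Mt1 (0.58 instead of 0.62), Mt2 (0.65 instead of 0.69) and Srsy (1.01 instead of 1.74) were smaller. The prior degrees of freedom of the variance fit, of which a lower number asks for a larger variance before a call is made, were 4.87 without mouse 4 and 6.21 with all mice, so the lost calls do not show that mouse 4 set the spread of the 21 genes. Without mouse 2 limma called 34 probe sets, with prior degrees of freedom of 5.33, and the SDs of 23 of the 25 genes were larger, those of Acot5 (1.08 instead of 1.15) and Cyp7a1 (0.12 instead of 0.71) smaller. Without mouse 3 it called 30, and 16 of the 25 SDs were smaller.

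Single mice set much of the spread of several of these genes. The SD with all mice was over 1.5 times that without a single mouse for 17 of the 25 named genes that passed, and for 63 of the 116 other named genes. Leaving out the most extreme of 5 values lowers an SD also where the values differ by chance alone. How often chance gives a factor of 1.5 was not computed, so these counts are no measure of an excess. Mouse 3 had the lowest values of Orm2 (9.37), of Nnmt (8.09), which encodes nicotinamide N-methyltransferase, and of the metallothionein gene Mt2 (11.03), and the highest value of Mup3 (11.85), a major urinary protein gene. Without mouse 3 the SDs of these genes were 0.36, 0.49, 0.44 and 0.40, from 0.99, 0.90, 0.69 and 0.82 with it, and their limma adjusted p values lay between 0.129 (Mt2) and 0.299 (Mup3). Mouse 5 had the lowest values of the carboxylesterase gene Ces3b (8.56) and the sulfotransferase gene Sult2a8 (8.84) and the highest of Mybl1 (8.83), a gene of the Myb family of transcription factors. Their SDs fell from 1.14, 0.87 and 1.19 to 0.42, 0.33 and 0.62 without that mouse, with limma adjusted p values of 0.0519, 0.157 and 0.0609. Mybl1 lay below the brightness floor in mouse 3 (5.53, floor 5.79), so its SD rests partly on a value near background. The SD of Sprr1a was 0.99 without mouse 5, with a limma adjusted p of 0.0017. Saa2 was highest in mouse 1 (9.67), without which its SD was 0.58 (limma adjusted p = 0.118), and the SD of Srsy was 1.01 without mouse 4. The transporter gene Slco1a4 (mean 7.07, SD 1.14) had values of 8.42 and 8.14 in mice 1 and 5 and of 5.94 to 6.66 in the others. Cmah, which encodes an enzyme that modifies sialic acid, spanned 6.14-fold (SD 1.13). Without mouse 3 its SD was 0.89 and its limma adjusted p 0.0618. Without mouse 4, the limma adjusted p of the 15 genes with the largest variance for their level lay between 0.0883 and 0.168 (Mt2), while the SDs of Sprr1a, Ces3b and Slco1a4 were 1.73, 1.32 and 1.29, larger than with it.

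**Figure D1:**
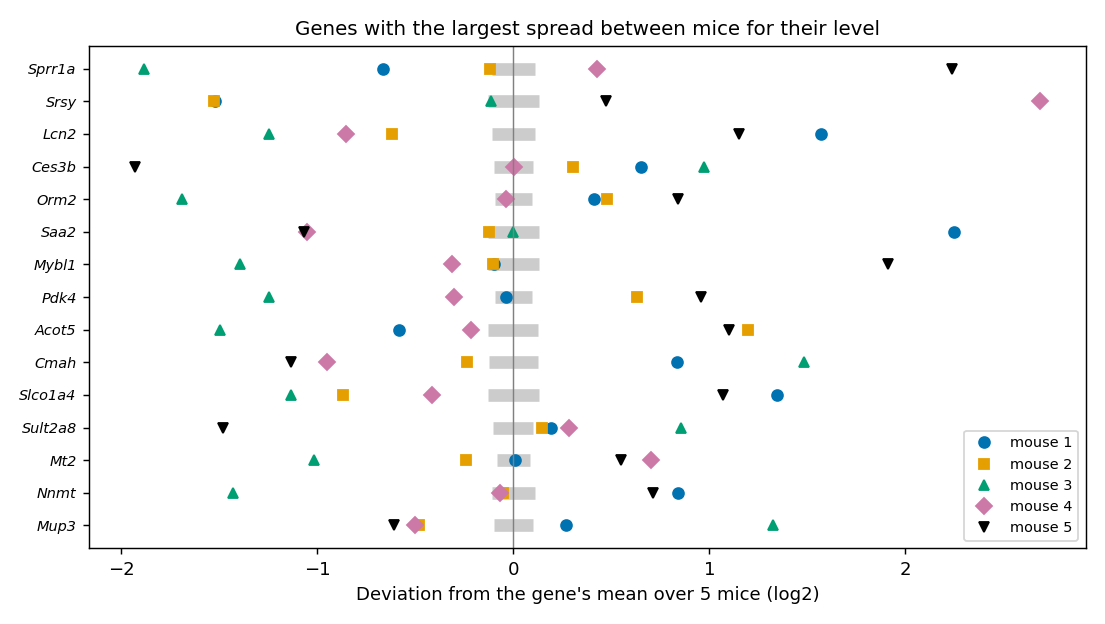
Deviation of each mouse (points, log2) from the mean over 5 mice for the 15 named genes with the largest variance for their level. Grey bars span 1 expected SD to each side of 0, and Sprr1a lies 17.5-fold apart between its lowest and highest mouse.

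Target genes of PPARA, the receptor that drives fatty acid oxidation in liver, differed in how far they spread between mice, and several had small spans. Cpt1a, which encodes the enzyme that admits long-chain fatty acids to mitochondria, had a mean of 11.70 ± 0.04 (SD, n = 5), a 1.08-fold span. Ehhadh, of peroxisomal oxidation, had 13.52 ± 0.06, and the omega-hydroxylase genes Cyp4a10 and Cyp4a14 had 13.19 ± 0.11 and a span of 1.08-fold around 13.6. The highest value on an array was 14.00 to 14.12, and whether saturation compressed differences among the brightest genes was not examined. Ppara itself had 10.71 ± 0.15, the pantetheinase gene Vnn1 12.24 ± 0.13, the fatty acid transporter gene Cd36 12.20 ± 0.12, the lipid droplet gene Plin2 13.10 ± 0.13 and the thioesterase gene Acot1 11.13 ± 0.19. Fgf21, a hormone gene of the fasting response, lay near the floor at 6.08 ± 0.33 and did not exceed it on all arrays.

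All 40 measured genes of PPARA fatty acid oxidation targets exceeded the floor in all mice, and the list varied together by small amounts (SD 0.0845 against a median of 0.0306 for random lists, permutation adjusted p = 0.000617). Its mean deviation was -0.05, 0.12, -0.10, 0.03 and 0.0033 in mice 1 to 5, and 25 of the 40 genes were highest in mouse 2. Acot5, a peroxisomal thioesterase gene, had the widest spread of the list (mean 7.61, SD 1.15, 6.48-fold) and was the 1 member whose variance passed over all genes, against 3 adjusted over the list alone. Its limma adjusted p was 0.0506 without mouse 2, 0.0540 without mouse 3 and 0.0883 without mouse 4, with SDs of 1.08, 0.91 and 1.32. Acot3 (SD 0.43, and 0.21 without mouse 3), Acot4 (0.34, and 0.15 without mouse 3) and the peroxisomal transporter gene Abcd2 (0.20) followed.

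PPARA targets other than oxidation also varied together (SD 0.0948, permutation adjusted p = 0.0026), with deviations of -0.0062, 0.14, -0.12, -0.04 and 0.03 in mice 1 to 5, and 28 of 30 measured genes exceeded the floor in all mice. The permutation adjusted p was 0.099 without mouse 2, 0.301 with each gene divided by its SD and 0.0849 against random lists matched on level and SD. Pdk4 led this list with 11.95 in mouse 5, 11.62 in mouse 2 and 9.75 in mouse 3, and was the 1 member called over all genes, against 4 adjusted over the list alone. Its limma adjusted p was 0.0824 without mouse 3 and 0.103 without mouse 4, with SDs of 0.58 and 0.97, against 0.86 with all mice. The lipolysis inhibitor gene G0s2 had an SD of 0.50, the uncoupling protein gene Ucp3 of 0.44 and Rab30 of 0.37.

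**Figure D2:**
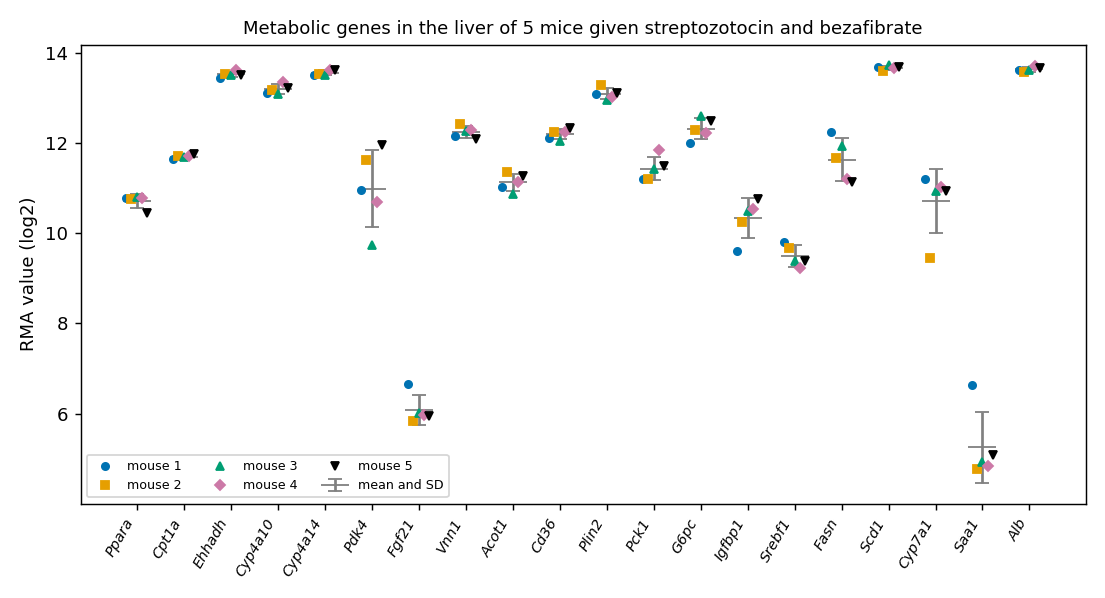
RMA values (log2) of 20 metabolic genes in the liver of each of the 5 mice (points), with mean and SD (grey bars). Cpt1a, Scd1 and Alb have SDs of 0.04 to 0.05, against 0.86 for Pdk4 and 0.71 for Cyp7a1.

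Genes of fatty acid and triglyceride synthesis deviated in step between the mice. Fasn (fatty acid synthase) was 12.23 in mouse 1 and 11.13 in mouse 5 (mean 11.63 ± 0.47, SD, n = 5), and Thrsp, which encodes a regulator of lipogenesis, was 10.29 and 8.51 in the same mice. The mean deviation of the 23 genes was 0.29, -0.02, 0.15, -0.20 and -0.22 in mice 1 to 5 (SD 0.223 against 0.0387 for random lists, permutation adjusted p = 0.000411). Of the 23 genes, 17 were highest in mouse 1. Kupffer cell and macrophage (0.33), skeletal muscle (0.51), erythroid (0.35) and stellate cell markers (0.15) were highest in mouse 1 too, so a different mix of cells was not separated from a change within cells. Hepatocyte markers deviated by 0.04 and adipocyte markers by -0.06 in mouse 1, against 0.29 for the synthesis genes. All 23 synthesis genes exceeded the floor in all mice. Pklr (SD 0.58), of glycolysis, and the lipase-family gene Pnpla3 (0.46) were among the widest, whereas the desaturase gene Scd1, also near the top of the array scale, had 13.67 ± 0.04 and Srebf1, a transcription factor gene of the pathway, 9.50 ± 0.24. Thrsp was the 1 member called over all genes, against 11 adjusted over the list alone, and its limma adjusted p was 0.065 without mouse 1, 0.0638 without mouse 2, 0.0677 without mouse 3 and 0.168 without mouse 4. Its SD was 0.61 without mouse 1, against 0.72 with all mice, and larger without mouse 2 (0.83), mouse 3 (0.75) or mouse 4 (0.78).

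Cholesterol synthesis and uptake genes varied together as well, with deviations of 0.17, 0.08, 0.10, -0.11 and -0.25 in mice 1 to 5 (SD 0.172, permutation adjusted p = 0.000411). All 20 measured genes exceeded the floor, 17 of them were lowest in mouse 5, and 0 had a variance that passed, over all genes or adjusted over the list alone. The widest were Mvd (SD 0.32), Tm7sf2 (0.32), Pmvk (0.29) and Stard4 (0.29).

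Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, was 9.46 in mouse 2 and 10.94 to 11.20 in the other mice. In the same mouse Nr0b2, which encodes a repressor of Cyp7a1, was 10.61, against 9.59 to 9.83 in the others. Cyp7a1 was the 1 member of bile acid synthesis and transport called over all genes (3 adjusted over the list alone), and without mouse 2 its SD was 0.12 instead of 0.71 (limma adjusted p = 0.991). Without mouse 4 its limma adjusted p was 0.143, with a larger SD of 0.79. The list as a whole deviated by 0.08, 0.04, 0.05, 0.01 and -0.18 in mice 1 to 5, a joint variation (SD 0.105, permutation adjusted p = 0.0072) that was gone without mouse 5 (SD 0.0277, permutation adjusted p = 0.832). It did not pass against random lists matched on level and SD either (permutation adjusted p = 0.145). Cyp7b1 (SD 0.54) and the sterol transporter gene Abcg8 (0.24) were also among its widest members, and 18 of 20 genes exceeded the floor in all mice.

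Genes of glucose production did not vary together as a list. Pck1, of gluconeogenesis, had 11.43 ± 0.26 (SD, n = 5) and G6pc, the catalytic subunit of glucose-6-phosphatase, 12.32 ± 0.24. Igfbp1, a gene repressed by insulin, was 9.61 in mouse 1 and 10.25 to 10.77 in the others. Irs2, of insulin signalling, was 7.64 in mouse 1 and 8.17 to 8.28 in the others. G6pc (11.998) and Pck1 (11.202, against 11.203 in mouse 2) were also lowest in mouse 1. Of the 20 genes of their list, 5 were lowest and 5 highest in mouse 1. The 20 genes of gluconeogenesis and insulin-repressed genes had a list SD of 0.039, below the 0.0468 of random lists (permutation adjusted p = 0.724), with 0 members called over all genes and 1 adjusted over the list alone. Glycolysis and glycogen genes (16 measured) had a list SD of 0.0811 (permutation adjusted p = 0.0799, and 0.00705 with the median over members), with the glycogen-targeting genes Ppp1r3g (SD 0.45) and Ppp1r3b (0.39) widest. Ketogenesis genes (5 measured) had a list SD of 0.0908 (permutation adjusted p = 0.236), with Bdh2 (0.42) and Slc16a6 (0.20) widest. In each of these lists 0 members were called over all genes and 1 adjusted over the list alone.

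Mitochondrial respiratory chain genes showed the smallest joint variation among the lists that passed. The 55 genes deviated by 0.01, 0.06, 0.03, -0.02 and -0.08 in mice 1 to 5 (SD 0.0554, permutation adjusted p = 0.0261), and 33 of them were lowest in mouse 5. Without mouse 5 the SD was 0.0336 (permutation adjusted p = 0.578), and without mouse 2 the permutation adjusted p was 0.0701. With arrays centred on their medians it was 0.152, and against random lists not matched on level 0.122. Ndufb3 (SD 0.21), Ndufs4 (0.20), Ndufs6 (0.18) and Atp5e (0.17) were widest, and 0 members passed alone. TCA cycle genes did not vary together (list SD 0.0387, permutation adjusted p = 0.663), with Pdhx (SD 0.20) and Dlat (0.18), both of the pyruvate dehydrogenase complex, widest, and 0 of 20 members passed over all genes or adjusted over the list alone. Amino acid catabolism and urea cycle genes varied together, with deviations of 0.07, 0.11, -0.08, 0.01 and -0.12 (SD 0.0976, permutation adjusted p = 0.0014). Their widest members were Prodh (SD 0.40), Hal (0.32), the urea cycle gene Otc (0.28) and Oat (0.26), and 0 of 29 were called over all genes or adjusted over the list alone.

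Acute-phase and inflammation genes varied together, with deviations of 0.23, -0.10, -0.13, -0.12 and 0.12 in mice 1 to 5 (SD 0.165, permutation adjusted p = 0.000411). Mouse 1 also had the highest deviations of the Kupffer cell and macrophage (0.33), skeletal muscle (0.51) and erythroid lists (0.35), so a different mix of cells was not separated from a response within cells. Lcn2 was 10.93 in mouse 1 and 10.52 in mouse 5, against 8.12 to 8.75 in the others. Saa1, a serum amyloid gene, was 6.64 in mouse 1 and 4.77 to 5.08 in the others, below the floor there. The metallothionein genes Mt1 and Mt2 were highest in mouse 4 (11.44 and 12.75) and lowest in mouse 3 (9.98 and 11.03), as was Orm3 in mouse 3 (7.17). Of 31 tested members, 6 were called over all genes and 10 adjusted over the list alone, and without mouse 4 the limma adjusted p of Lcn2, Saa2 and Orm2 was 0.0883 (with larger SDs of 1.36, 1.41 and 1.15), that of Orm3 0.137, that of Mt2 0.168 and that of Mt1 0.228. Without mouse 3 the SD of Orm3 was 0.33 instead of 0.80 and its limma adjusted p 0.602, that of Orm2 0.297, that of Mt1 0.153 and that of Mt2 0.129. Without mouse 2 the limma adjusted p was 0.0835 for Orm3 and 0.0767 for Mt1, with larger SDs of 0.81 and 0.67, and without mouse 1 it was 0.118 for Saa2. When each gene was divided by its SD before averaging, the list no longer varied together (permutation adjusted p = 0.343).

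Cell cycle genes were highest in mouse 5. Plk1, which encodes a mitotic kinase, was 8.46 in mouse 5 and 6.11 to 6.74 in the others, Cdk1 was 9.20 against 7.82 to 8.01, and the cyclin genes Ccnb2 and Ccna2 were 9.41 against 7.89 to 8.29 and 8.06 against 6.52 to 6.96. The list of cell cycle and proliferation genes deviated by 0.50 in mouse 5 and by 0.01, -0.19, -0.21 and -0.11 in mice 1 to 4 (SD 0.295, permutation adjusted p = 0.000411). Of 24 tested genes, 22 were highest in mouse 5, and 20 of 28 measured ones exceeded the floor in all mice. Without mouse 5 the SD was 0.102, and Plk1, the 1 member called over all genes (12 adjusted over the list alone), had an SD of 0.29 instead of 0.92 and a limma adjusted p of 0.712. The limma adjusted p of Plk1 was 0.0719 without mouse 2 and 0.137 without mouse 4, with larger SDs of 0.94 and 1.02.

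Genes of the p53 and DNA damage response deviated by 0.06, 0.12, -0.26, -0.12 and 0.19 in mice 1 to 5 (SD 0.185, permutation adjusted p = 0.000411), led by Gadd45b (SD 0.55), Eda2r (0.50), Zmat3 (0.33) and Btg2 (0.30). No member passed over all genes, and 2 did adjusted over the list alone. Interferon response genes deviated by 0.13, -0.08, 0.10, -0.11 and -0.04 (SD 0.109, permutation adjusted p = 0.0032), with Usp18 (SD 0.34), Rsad2 (0.29), Psmb8 (0.26) and Oasl1 (0.26) widest. Against random lists matched on level and SD the interferon list did not pass (permutation adjusted p = 0.0902). Genes of antigen presentation by MHC class II deviated by 0.15, -0.20, 0.06, -0.13 and 0.12 (SD 0.155, permutation adjusted p = 0.0337), with H2-Aa (SD 0.25), Cd74 (0.22), H2-DMa (0.21) and H2-Ab1 (0.21) widest. This adjusted p was 0.0543 without mouse 1 and 0.125 without mouse 2. It was 0.213 against random lists matched on level and SD, 0.0553 with arrays centred on their medians and 0.0683 without the member with the largest SD, a setting added after the data were seen. Markers of Kupffer cells and macrophages, which present antigen, deviated by 0.33, -0.16, -0.01, -0.21 and 0.06 in mice 1 to 5, so the share of such cells was not separated from expression within them for either immune list. In neither immune list did a member pass over all genes or adjusted over the list alone. ER stress and unfolded protein response genes (list SD 0.0635, permutation adjusted p = 0.19) and heat shock response genes (0.0568, permutation adjusted p = 0.465) did not vary together. The widest members of these were Asns (SD 0.43) and Atf3 (0.32), and Hspb1 (0.32) and Cryab (0.20), with 0 calls over all genes or adjusted over the list alone.

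Male-biased liver genes were highest and female-biased ones lowest in mouse 3. The list of male-biased liver genes deviated by 0.43 in mouse 3 and by 0.10, -0.02, -0.18 and -0.34 in mice 1, 2, 4 and 5 (SD 0.294, permutation adjusted p = 0.000411), with 12 of 16 tested genes highest in mouse 3. Elovl3, a fatty acid elongase gene, was 11.42 in mouse 3 and 9.58 in mouse 5, the complement gene C8b was 10.73 and 9.38, Mup3 was 11.85 and 9.91, and Cyp7b1 was 10.32 and 8.84. Female-biased liver genes deviated by -0.41 in mouse 3 and by 0.05, 0.07, 0.17 and 0.12 in the others (SD 0.233, permutation adjusted p = 0.000411), and 7 of 9 were lowest in mouse 3, as were Cyp2b13 (6.99 against 8.22 to 9.31) and Cyp17a1 (9.90 against 10.57 to 10.86). Without mouse 3 the male-biased list still varied together (SD 0.194, permutation adjusted p = 0.000529), with mouse 5 lowest, and the female-biased list did not (SD 0.0563, permutation adjusted p = 0.638). Over all genes 2 male-biased members (Elovl3 and Mup3) and 1 female-biased member (Cyp2b13) were called, against 10 and 3 adjusted over the list alone. The limma adjusted p of Elovl3 was 0.0549 without mouse 2, 0.137 without mouse 4 and 0.0671 without mouse 5, and that of Mup3 was 0.299 without mouse 3 and 0.137 without mouse 4. The SD of Mup3 was 0.40 without mouse 3 and 0.89 without mouse 4, against 0.82 with all mice. The SD of Elovl3 was larger without mouse 2 (0.79) and mouse 4 (0.86) than with all mice (0.75), and 0.39 without mouse 5. The limma adjusted p of Cyp2b13 was 0.055, 0.303 and 0.185 without mice 2, 3 and 4, and its SD was 0.96, 0.47 and 0.76, against 0.86 with all mice. Cyp3a44 (SD 0.27) had the smallest spread of the female-biased genes named here.

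Xenobiotic-inducible enzymes deviated by 0.09, 0.02, -0.26, -0.0071 and 0.17 in mice 1 to 5 (SD 0.161, permutation adjusted p = 0.000411). Cyp2c55 was 9.44 in mouse 5 and 7.41 in mouse 3, Cyp2c37 was 10.56 in mouse 1 and 8.81 in mouse 3, and Hmox1, the heme oxygenase gene, was 9.84 in mouse 5 and 8.46 to 8.92 in the others. Of 29 tested genes, 18 were lowest in mouse 3, and without that mouse the list SD was 0.0784 and still passed. Cyp2b13 and Cyp2c55 were called over all genes, against 15 adjusted over the list alone, and Cyp2c55 lost its call without mouse 2, 3, 4 or 5 (limma adjusted p = 0.0719, 0.134, 0.168 and 0.17). The SD of Cyp2c55 was 0.75 with all mice, 0.86, 0.65 and 0.84 without mice 2, 3 and 4, and 0.45 without mouse 5. Cyp2b13 lost its call without mouse 2, 3 or 4 (limma adjusted p = 0.055, 0.303 and 0.185), with SDs of 0.96, 0.47 and 0.76 instead of 0.86.

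Genes of the circadian clock output phase deviated by 0.16, -0.24, -0.22, 0.22 and 0.07 in mice 1 to 5 (SD 0.215, permutation adjusted p = 0.000617). Ciart was 5.83 in mouse 3 and 6.90 to 7.54 in the others, and Usp2 (SD 0.48), Per3 (0.40) and Per1 (0.40) followed. No member passed over all genes, and 5 did adjusted over the list alone. The opposite phase had 4 tested genes, too few for the list test. Of these, Arntl was 6.34 in mouse 4 and 6.90 to 7.39 in the others, and Nfil3 was 6.93 and 7.55 to 7.96. Divided by their SDs, the output genes no longer varied together (permutation adjusted p = 0.206).

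Pericentral hepatocyte genes, expressed around the central vein, deviated by 0.10, -0.0023, 0.02, -0.13 and 0.0083 in mice 1 to 5 (SD 0.0808, permutation adjusted p = 0.0392), and this adjusted p was 0.136 without mouse 1 and 0.372 without mouse 4 (SD 0.046). It was 0.343 with each gene divided by its SD, and 0.0588 and 0.34 against random lists not matched on level and matched on level and SD. Slc13a3 (SD 0.41), Gulo (0.34), Cyp1a2 (0.30) and Slc1a2 (0.28) were widest. Periportal hepatocyte genes did not pass (list SD 0.0826, permutation adjusted p = 0.0566), and did without mouse 4 (0.0357) or mouse 5 (0.0237), with arrays centred on their medians (0.0491), with the median over members (0.0244) and with the stricter filter (0.047). The apolipoprotein gene Apoa4 (SD 0.79, 11.32 in mouse 5) and Pigr (SD 0.71, 7.88 in mouse 5), a receptor for secreted antibodies, were called over all genes. The limma adjusted p of Apoa4 was 0.053 without mouse 2 and 0.143 without mouse 4, and that of Pigr was 0.0767, 0.0629, 0.168 and 0.303 without mice 2, 3, 4 and 5. The SD of Apoa4 was larger without mouse 2 (0.82) or mouse 4 (0.82), as was that of Pigr without mouse 2, 3 or 4 (0.79, 0.79 and 0.81), while that of Pigr was 0.33 without mouse 5. Of the pericentral genes 0 passed over all genes and 4 adjusted over the list alone, and of the periportal genes 2 and 5.

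Hepatocyte markers did not vary together. Alb (albumin) had 13.64 ± 0.05 (SD, n = 5), near the top of the array scale, where saturation was not examined, and the 15 genes of the hepatocyte list had a list SD of 0.0288 (permutation adjusted p = 0.719), with the transcription factor genes Cebpa (SD 0.24) and Hnf4a (0.13) widest. Kupffer cell and macrophage genes varied together, with deviations of 0.33, -0.16, -0.01, -0.21 and 0.06 in mice 1 to 5 (SD 0.213, permutation adjusted p = 0.000411). Of these 17 genes, 15 were highest in mouse 1, where Adgre1 was 9.24 (8.20 to 8.47 in the others), Timd4 7.86 (6.89 to 7.06), Lyz2 10.57 (9.71 to 10.04) and Marco 6.67 (5.91 to 6.25). No member passed over all genes, and 3 did adjusted over the list alone. Without mouse 1 the SD was 0.123 and the list still passed.

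Markers of skeletal muscle and of erythroid cells also varied together. The 7 tested muscle genes, of 14 measured, deviated by 0.51 in mouse 1 and by -0.22, -0.05, -0.04 and -0.19 in mice 2 to 5 (SD 0.294, permutation adjusted p = 0.000617), and without mouse 1 the SD was 0.0919 (permutation adjusted p = 0.219). Atp2a1 was 7.50 in mouse 1 and 6.17 to 6.60 in the others, Mb (myoglobin) 7.50 and 6.57 to 6.78, Ckm 7.29 and 6.44 to 6.63, and Acta1 7.86 and 6.93 to 7.38. The 5 erythroid genes deviated by 0.35 in mouse 1, -0.34 in mouse 4 and 0.02, -0.01 and -0.02 in mice 2, 3 and 5 (SD 0.247, permutation adjusted p = 0.0074), led by Tfrc (SD 0.58), Alas2 (0.55), Klf1 (0.20) and Slc4a1 (0.19). When each gene was divided by its SD before averaging, the erythroid list no longer varied together (permutation adjusted p = 0.062). No gene of these lists passed over all genes, and 4 muscle genes and 2 erythroid genes did adjusted over the list alone.

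The remaining cell type lists and the fibrosis list did not pass, although some did in other settings. Endothelial cell genes (list SD 0.0572, permutation adjusted p = 0.637) were led by Gata4 (SD 0.17) and Stab2 (0.15), and stellate cell and fibroblast genes (0.0874, permutation adjusted p = 0.0968) by Acta2 (0.23) and Pdgfra (0.21). The stellate list passed without mouse 4 (permutation adjusted p = 0.0437) and with each gene divided by its SD (0.0277), and its SD was 0.0288 without mouse 1, as that of the endothelial list was 0.0309. Fibrosis and extracellular matrix genes (0.0791, permutation adjusted p = 0.0686) passed without mouse 4 (0.0222) and with each gene divided by its SD (0.00768), and had Mmp12 (SD 0.60) and Lgals3 (0.29) as widest members. Cholangiocyte genes (0.0619, permutation adjusted p = 0.41) were led by Epcam (SD 0.29) and Sox9 (0.22), T and NK cell genes (0.0771, permutation adjusted p = 0.19) by Cd8b1 (0.15) and Ccl5 (0.15), and B and plasma cell genes (0.101, permutation adjusted p = 0.0799) by Cd79b (0.22) and Xbp1 (0.17). The T and NK cell list passed with each gene divided by its SD (permutation adjusted p = 0.0132) and against random lists matched on level and SD (0.0207). With no filter on dim probe sets, the B cell and acinar lists passed (permutation adjusted p = 0.0214 for each). Without mouse 3 the list SD was 0.06 for B and plasma cell genes and 0.0388 for adipocyte genes. Neutrophil and monocyte genes (0.0704, permutation adjusted p = 0.439) had 2 of 16 measured genes above the floor in all mice and were led by Csf3r (SD 0.20) and Elane (0.14). Adipocyte genes (0.0809, permutation adjusted p = 0.19) were led by Fabp4 (SD 0.26) and Pparg (0.25), and pancreatic acinar cell genes (0.0724, permutation adjusted p = 0.218) by Try5 (0.30) and Ctrb1 (0.22). Of the genes in these lists, 0 were called over all genes, and adjusted over the list alone only 1 fibrosis gene was.

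Of the 37 lists tested, 20 varied together and 17 did not.

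**Figure D3:**
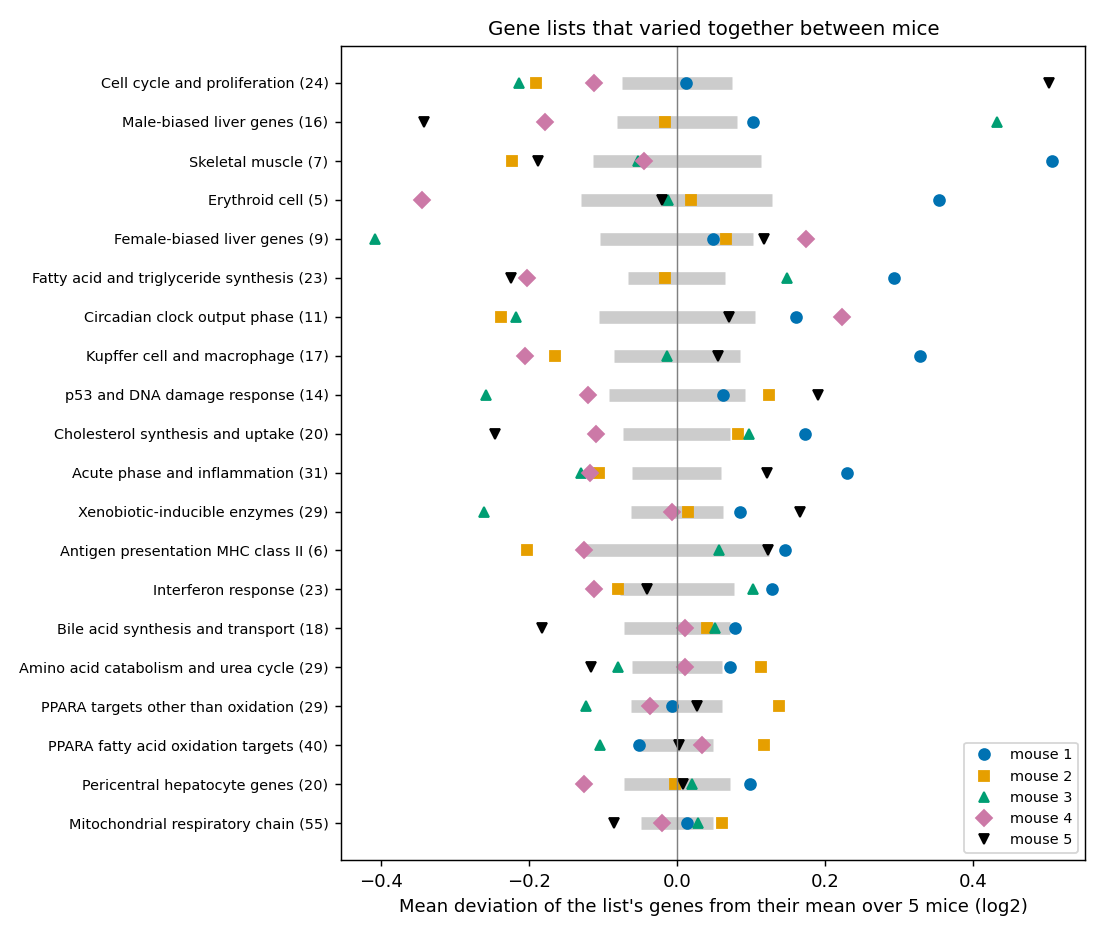
Mean deviation (log2) of each mouse (points) from the mean over 5 mice, for the 20 gene lists that varied together, with the number of tested genes in parentheses. Grey bars reach the 95th percentile of the SD of random lists to each side of 0, and the cell cycle list of mouse 5 and the skeletal muscle list of mouse 1 lie at 0.50 and 0.51.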

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

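The tests of genomic DNA and of gene families were set before their results were seen, and the other 4 tests in this part were chosen after. For gene families, a demand that the value also exceed 25% by more than 2 SE was added once the value was known. Of 180 values examined (array measures, list means and named genes), 22 had 1 mouse whose gap to the nearest other mouse exceeded 0.71 of the whole range, the 95% critical value of Dixon's test for 5 samples, where chance gives about 1 in 20, or 9. That share holds for values not picked by their spread, and many named genes were picked for a large one, so the 22 are no measure of an excess. By mouse, 10 concerned mouse 1, 2 each mice 2, 3 and 4, and 6 mouse 5.

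In mouse 4 the median of the olfactory and vomeronasal receptor probe sets was 4.64, against 4.21 to 4.33 in the others (0.726 of the range). Eif2s3y was lowest there (8.504, 0.726 of the range). All 15 tested Srsy probe sets, of 19, spread beyond their expected variance, but the filter on the mean favours those that mouse 4 raised. A general rise of background does not account for Srsy: receptor probe sets were raised by a median of 0.32, which is 9.63% of the 3.30 by which the Srsy probe sets were raised. More transcription of the Y chromosome as a whole was not seen either, since Kdm5d, Eif2s3y and Uty deviated by a mean of -0.21 (SE 0.09, 3 genes) in mouse 4. Genomic DNA left in the RNA of mouse 4 is a candidate explanation. Of 67 probe sets assigned to several genes, of which at least 50% lie on the Y chromosome, 98.5% were brightest in mouse 4, by a median of 2.62. This share has to be read against the receptor probe sets, of which 76.0% were brightest in mouse 4 too. The named Srsy probe set was also higher in mice 3 (6.83) and 5 (7.41) than in mice 1 (5.42) and 2 (5.41), and DNA in the RNA of mice 3 and 5 was not tested. The 67 probe sets stem from few gene families, the extraction included a DNase step, and transcription of these families themselves was not measured apart from DNA. They were used because the set first planned had no members. The design, with 1 group, gives no biological explanation to set against genomic DNA.

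In mouse 5 the cell cycle genes Cdk1 (0.865 of the range), Ccnb2 (0.741), Plk1 (0.733) and Ccna2 (0.7102) stood apart on the high side. The 24 tested genes of the list deviated by 0.50 there. Leukocytes in this liver stay open: 20 markers of T, NK, B, neutrophil and monocyte cells deviated by 0.0247 (SE 0.0219) in mouse 5, and 15.7% of random lists deviated as far. Many of these markers lie near the floor, where a small share of such cells cannot be told apart from none. Apart from this, no explanation was tested. The design has 1 group, and the amount of bezafibrate per mouse is not given, so a difference in it could not be tested.

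In mouse 3 the female-biased list stood apart on the low side (0.786 of the range), with the male-biased list at its highest. Signal shared between near-identical members of the Mup, Cyp, Sult, Ugt, Serpina and Acot families does not account for the whole of it. Without these families the male-minus-female difference in mouse 3 was 0.63 (SE 0.10 over 12 genes, taken as independent). That was 75.1% (SE 11.4 points) of the full 0.84 and only just past the 75% set beforehand. Signal shared within other families was not tested. A higher STAT5 activity downstream of growth hormone, which drives male-biased expression, may contribute and stays open. Its target genes Socs2, Cish, Igf1 and Igfals deviated by 0.16 (SE 0.05) in mouse 3, a value 1.32% of random lists reached. They deviated by 0.28 in mouse 1, where the male-minus-female difference was 0.05. None of them was highest in mouse 3: Cish and Igfals were so in mouse 1, Socs2 in mouse 4 and Igf1 in mouse 5. The design, with 1 group, gives no further biological explanation that could be tested. A difference in the amount of bezafibrate could not be, since it is not given per mouse.

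In mouse 1 the skeletal muscle list (0.756 of the range), Ckm (0.773) and Mb (0.770) stood on the high side. The stellate cell and fibroblast list (0.722) and Acta2 (0.858, 9.17 against 8.63 to 8.71) did so in the same mouse, as did the Kupffer cell genes Adgre1 (0.741) and Timd4 (0.826), Saa1 (0.838) and Fgf21 (0.777, 6.66 against 5.83 to 6.01). Irs2 was lowest in mouse 1 (0.821). In mouse 2 Cyp7a1 stood on the low side (0.848) and Nr0b2 on the high side (0.762). In mouse 3 Hnf4a was lowest (0.803, 11.34 against 11.61 to 11.67). In mouse 5 the bile acid synthesis and transport list (0.743) and Ppara (0.856, 10.45 against 10.75 to 10.80) were lowest.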

How the results depend on the processing

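The settings that leave out the Srsy probe sets or the member of a list with the largest SD were chosen after seeing the data, the others before. The cause of the changes below was not tested, except that the prior degrees of freedom of the variance fit, where a lower number makes calls harder, were 4.87 without mouse 4 and 3.45 with all probe sets, against 6.21. No paired analysis was possible because the mice form 1 group. Signal over background limits the lists of leukocyte, acinar, adipocyte and cholangiocyte genes, many of which lie under the floor.

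The count of 52 probe sets with a variance above expectation was 142 with each array centred on its median, 18 with the stricter filter, 18 without the robust step, 24 without the trend on level, 0 (1385 at an unadjusted p under 0.05) when limma tested all probe sets with or without 1 symbol, and 31 without the Srsy probe sets. It lay between 0 (without mouse 4) and 69 (without mouse 1) when 1 mouse was left out. With quantile normalization it was 37, all among the 52, and with no filter 40.

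The count of lists that varied together lay between 16 and 22 in all settings, and 9 of the 20 lists kept the call in each of 15 settings. The other 11 lost it in at least 1, and 7 lists gained it in at least 1. The list counts above the floor (597 genes) lay between 531 and 619. List SDs under the settings that ended or made a call follow. With arrays centred on their medians, the respiratory chain (0.0776) and MHC class II (0.161) lost the call and periportal genes (0.111) gained it. With the median over members, glycolysis (0.0858) and periportal genes (0.0701) gained it. Acute-phase, xenobiotic-inducible and female-biased genes kept it in that setting, with SDs of 0.0725, 0.0943 and 0.132, smaller than with the mean (0.165, 0.161 and 0.233). With each gene divided by its SD, other PPARA targets (0.373), acute phase (0.339), circadian output (0.599), pericentral (0.385) and erythroid genes (0.768) lost it, and fibrosis (0.601), T and NK cell (0.708) and stellate genes (0.624) gained it. Against random lists not matched on level, the respiratory chain (0.0554) and pericentral genes (0.0808) lost it. Against lists matched on level and SD, other PPARA targets (0.0948), bile acid (0.105), interferon (0.109), MHC class II (0.155) and pericentral genes (0.0808) lost it and T and NK cell genes (0.0771) gained it. With no filter, B cell (0.102) and acinar genes (0.0816) gained it, and with the stricter filter, periportal genes did (0.0826). Without the member with the largest SD, MHC class II (0.14) lost it, and glycolysis (0.0933), fibrosis (0.0849) and periportal genes (0.101) gained it.

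Leaving out 1 mouse in turn gave list SDs of 0.0639 to 0.109 for other PPARA targets, 0.0277 to 0.121 for bile acid, 0.0336 to 0.0633 for the respiratory chain, 0.123 to 0.176 for MHC class II, 0.0578 to 0.0901 for fibrosis, 0.0563 to 0.267 for female-biased, 0.046 to 0.0933 for pericentral, 0.0595 to 0.094 for periportal, 0.0288 to 0.101 for stellate and 0.0919 to 0.339 for skeletal muscle genes. Single named genes were followed in 8 settings (both other normalizations, the mean over probe sets and each mouse left out), where 1036 SDs stayed on their side of the threshold, 69 lost and 22 gained a call. Some lists had under 5 tested members in a setting, which then gave no value.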

Other observations

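The comparisons in this part were chosen after the data had been seen. How far single members of a list differed between mice is a separate question from whether they moved in step, and the median SD of the members was set against that of level-matched random lists (two-sided permutation p, adjusted over 37 lists). Members of 19 lists spread more than random genes of their level and those of 3 lists less. Genes of gluconeogenesis and insulin repression, which did not vary together, still had a median member SD of 0.142, against 0.102 for random lists (permutation adjusted p = 0.0285), and periportal genes had 0.209 against 0.0977 (permutation adjusted p = 0.00067). The median member SD of the 40 PPARA oxidation genes was 0.093 against 0.0886, which did not pass (permutation adjusted p = 0.693). Hepatocyte markers (0.0544 against 0.0838, permutation adjusted p = 0.0148), respiratory chain genes (0.0728 against 0.0932, permutation adjusted p = 0.016) and fibrosis genes (0.0884 against 0.119, permutation adjusted p = 0.036) were the lists with narrower spread. Hepatocyte markers such as Alb lie near the top of the array scale. Saturation was not examined there, and the top bin of level may hold dimmer genes with a wider expected spread.

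Several genes that passed the variance test lay outside the lists and the naming rule. Smcp, a sperm mitochondrial protein gene that lies near Sprr1a on chromosome 3, was 9.21 in mouse 5 and 7.15 in mouse 3, and Sprr1a was highest and lowest in the same mice. Ces3a, the neighbour and paralog of Ces3b, was lowest in mouse 5 (10.98) and highest in mouse 3 (12.64), like Ces3b, and how far their probes share signal was not examined. The antioxidant enzyme gene Gpx3 was 9.90 in mouse 5 and 7.76 to 8.26 in the others, and Cd24a was 10.19 and 8.21 to 8.73. The transcription factor gene Onecut1 was 7.80 in mouse 5 and 8.52 to 9.69 in the others, and Egfr, the epidermal growth factor receptor gene, was 9.29 and 9.98 to 11.02. Otop1 was highest in mouse 3 (9.20) and Cxcl13, a B cell attractant gene, in mouse 1 (8.70). Without mouse 4, limma called 0 probe sets (864 at an unadjusted p under 0.05), which ended these calls too, along with those of all 25 named genes, although the SDs of 21 of the 25 were then larger.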
